A study of Mus musculus with 6 samples.

How the data were processed

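The data were RNA exome sequencing libraries of aberrant crypt foci dissected from the colon of mice aged 8 weeks, 3 Winnie-ApcMin and 3 Winnie-ApcMin with deletion of Tnf. RNA had been extracted from formalin-fixed, paraffin-embedded tissue and libraries made with an exome capture kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which mark the second group by a number and do not name Tnf, and its reading as the Tnf deletion was inferred from the series title. FastQC, STAR 2.5.1a, featureCounts and the genome build mm10 are named in the submitters' processing notes, and the gene annotation is not given in the sources used here.

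The deposited table holds 1 column per library and 14243 genes by symbol. Although it is named as raw counts, its values are not whole numbers. The deposited signal is a gene count divided by 1 factor per library. In each library 100% of the values were whole multiples of a constant step within the rounding of the table (a tolerance of 0.0056 normalised reads). The reciprocals of the steps, 0.9889, 1.4531, 1.2176, 0.7845, 0.851 and 0.8791, equalled the median-of-ratios size factors computed again from the recovered reads. In Winnie-ApcMin replicate 1 the step lies within about 1 percent of 1 read, so that the values of this library are near whole numbers as deposited, and its reads were recovered in the same way. The lowest sum of recovered reads of a gene was 11, so genes with fewer reads had been left out of the table. Recovered reads per library were 8632965 to 16426454, over 13878 to 14027 genes with at least 1 read. Fixed tissue gives fragmented RNA, capture favours targeted exons, and reads carry no molecular identifiers, so intervals and floors cover counting error only. Values are called normalised reads.

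Annotation came from GENCODE M21, which is on the same assembly as mm10, matched by symbol for 13750 of the genes (96.5%). GC content and length were available for 97% of the tested and 97.1% of the called genes. Genes were kept by filterByExpr with its defaults (minimum count 10), which left 11184. Because the values are not raw counts, the main test was limma 3.58.1 in R 4.3.3 on log2(normalised reads + 1), with a trended and robust empirical Bayes step, two-sided, Benjamini-Hochberg adjusted p under 0.05, and no covariate. The design fixed before the data were examined had named edgeR's quasi-likelihood test with TMM factors for raw counts. That fit was run on the recovered reads as an added alternative, with edgeR 4.0.16. It called 1531 genes, 1472 of them shared with limma. Log2 changes are differences of mean log2(normalised reads + 1), labelled Tnf-deleted minus Winnie-ApcMin, and understate the change of low genes. Adjusted p-values of genes in the text come from limma. Folds of genes without a read in a group were set against a floor of 3 reads per library.

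The lists, 37 in number, were written before the data were examined, from general knowledge of the colon, colitis, Wnt-driven tumours and TNF signalling, with markers of the other cell types a dissected lesion can hold. For the lists the fixed design had named camera on voom values with weights. Run as an alternative, this called 10 lists lower and 1 higher. In the main test the 33 lists with at least 5 tested members were tested with camera without weights at a preset correlation of 0.01, adjusted over these lists. With an estimated correlation 0 lists passed, and 0 had an unadjusted p under 0.05. The rotation test fry also called 0, with 4 at an unadjusted p under 0.05. Members were counted with p adjusted over all tested genes and adjusted over the list alone. Genes were named by a rule written before the data were examined. It takes Tnf, Muc2 and Apc, and the 12 largest changes in each direction among genes past the threshold with a mean of at least 50 normalised reads and groups that do not overlap. Unnamed gene models and antigen receptor segments are left out. It adds the members of each list with the smallest p, of which examples are given. A second set that also left out sex-linked, mitochondrial, non-coding, haemoglobin and histone genes was chosen after the values were seen. Tnf, which is below the filter, Muc2 and Apc were compared with exact permutation tests, whose smallest two-sided p for 3 libraries against 3 is 0.1. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 9 to 52.1), which does not show that they came from separate mice. They were counted as separate because the labels list them so.

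Alternatives covered normalisation, tool, filter, threshold, each library left out, the replicate number as a block, the pseudocount, thinning of the recovered reads to the smallest library, DESeq2 1.42.0 on the recovered reads, sex-linked and mitochondrial genes left out, and removal of the GC trend of each library with a natural spline of 5 degrees of freedom. Tests were checked on simulated data for 3 libraries against 3 at the real depths. Over 11242 simulated genes, limma recovered 66% of 2-fold and 99% of 4-fold changes, with 5.7% false among 174 calls. With a simulated GC trend between the groups, 38% of the calls were false, and 7.2% after removal of the trend. The simulated trend was the same in every library of 1 group. Real slopes, in log2 per 10 percent GC, were 0.249, 0.128 and 0.07 in Winnie-ApcMin and 0.015, -0.357 and -0.106 in the libraries labelled Tnf-deleted. Changes were planted only in genes above a minimum of reads. These shares therefore need not hold for the real libraries or for low genes. Camera recovered 1 of 1 planted list and called 0 of 33 without planting. The simulated genes were drawn independently of each other, so this check could not show false calls of lists that come from correlation between genes.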

Results

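Gene expression was measured by RNA sequencing after exome capture, in which libraries are enriched with probes for coding exons, in aberrant crypt foci of the mouse colon. Aberrant crypt foci are clusters of abnormal crypts and count among the earliest visible lesions of colorectal tumour formation. They were dissected from fixed, paraffin-embedded tissue of mice aged 8 weeks. All mice carried the Winnie allele, a missense mutation of the mucin gene Muc2 that causes spontaneous colitis, and the ApcMin allele, a truncation of the tumour suppressor Apc. The 6 libraries fell into 2 groups of 3, Winnie-ApcMin and Winnie-ApcMin with deletion of Tnf, which encodes the inflammatory cytokine tumour necrosis factor. The deposited values corresponded to 11313085, 16426454 and 13730069 reads in Winnie-ApcMin replicates 1 to 3. In the libraries labelled Tnf-deleted they corresponded to 8632965, 10006817 and 9945248 reads, and each of these was shallower than every Winnie-ApcMin library. The labels do not state that each library came from a separate mouse. The p-values therefore measure only the spread between these libraries, which may be technical.

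The comparison addressed how loss of Tnf changed gene expression in early colonic lesions of mice with colitis. Tnf itself (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007 in mm10) was close to the limit of detection. It had 1 read among 41469608 in the Winnie-ApcMin libraries and 11 reads among 28585030 in the libraries labelled Tnf-deleted. By replicate these were 0, 1 and 0 reads against 3, 5 and 3. The ratio of the rates was 16, with an exact 95% interval of 2.32 to 687 that covers counting error only. The exact two-sided permutation test of the normalised values gave p = 0.1, the smallest that 3 libraries against 3 allow. This direction goes against a deletion of Tnf. A count per gene does not tell which part of a gene was read, so these reads do not check the deletion. The sample titles mark this group only by a number and do not name Tnf, and its reading as the Tnf deletion is inferred from the series title. The group is called the libraries labelled Tnf-deleted throughout. Muc2 (chromosome 7, 141690340 to 141754693) had 9787 ± 3720 normalised reads in Winnie-ApcMin and 6677 ± 2030 in the libraries labelled Tnf-deleted (SD, n = 3 each, exact permutation p = 0.3, limma adjusted p = 0.331). Apc (chromosome 18, 34220924 to 34322552) had 6404 ± 721 and 7686 ± 657 (SD, n = 3 each, exact permutation p = 0.2, limma adjusted p = 0.21).

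**Figure D1:**
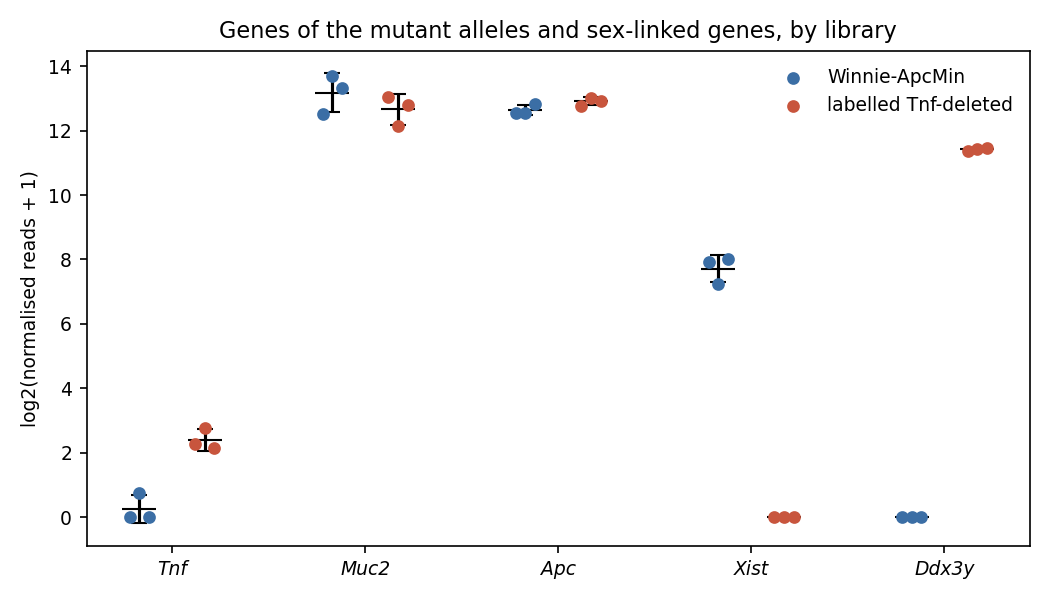
Normalised reads of Tnf, Muc2, Apc, Xist and Ddx3y on a log2(value + 1) axis, 1 point per library, with the group mean and SD in black. Tnf, Xist and Ddx3y separated the groups without overlap, Tnf at no more than 5 reads per library.

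Sex-linked genes divided the libraries exactly by group. Xist, the non-coding RNA that silences an X chromosome in female cells, had 214.9 ± 57.9 normalised reads in Winnie-ApcMin (SD, n = 3) and no read in any library labelled Tnf-deleted, at least 59.9-fold lower against a floor of 3 reads per library. Ddx3y, an RNA helicase gene of the Y chromosome, had no read in Winnie-ApcMin and 2736 ± 91.1 normalised reads in the libraries labelled Tnf-deleted (SD, n = 3), at least 1085.3-fold higher. The Y-linked histone demethylase gene Kdm5d was at least 91.9-fold higher, Uty had 1 read against 3073, and Eif2s3y had 8 reads against 3587, with the reads of the first group all in Winnie-ApcMin replicate 1. All 6 tested genes of the Y chromosome passed the test in the same direction. The labels give no sex. Genotype as labelled and the pattern of sex-linked transcripts coincided in all 6 libraries. Every difference described here is also a difference between libraries with a female and with a male pattern.

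Pearson correlations of libraries across genes were 0.964 to 0.987 within groups and 0.937 to 0.967 between groups. The first principal component of the 500 most variable genes held 50.6% of the variance and separated the groups (exact permutation p = 0.1, the smallest possible). On the second component, with 20.2%, Winnie-ApcMin replicate 1 stood at 22.98 and the other libraries of its group at -13.44 and -14.9.

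With a preset correlation, lists of smooth muscle, connective tissue and interferon-response genes were lower in the libraries labelled Tnf-deleted and the tested mitochondrially encoded list was higher, each with adjusted p = 0.647 with an estimated correlation. Of 11184 tested genes, 1526 (13.6%) differed at an adjusted p under 0.05 in limma, 814 higher and 712 lower in the libraries labelled Tnf-deleted. A change of at least 2-fold was seen in 210 of the higher and 284 of the lower genes. The groups did not overlap for 37.1% of the tested genes. For a single gene 10% is the share expected over all arrangements of the libraries, but genes are not independent, so the contrast is not a test. The count depended on single libraries: it was 595 without Winnie-ApcMin replicate 2, 550 without the library labelled Tnf-deleted replicate 2 and 324 without the library labelled Tnf-deleted replicate 3. Of the 111 genes named from the comparison that passed the test, 47 passed it in all 6 fits that left out 1 library. Of 33 tested gene lists camera called 12 with a preset correlation and 0 with an estimated one. Other splits of the 6 libraries into 3 and 3 gave up to 20 lists but 0 genes. Each of those splits mixes the groups on both sides, which widens the spread within a side, so its 0 genes do not speak against chance.

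The change of a gene was related to its base composition. Across genes, which are not independent replicates, the log2 change and the GC content of the transcript had a Spearman rho of -0.34, while rho with transcript length was 0.06. Median log2 changes ran from 0.29 in the 10% of genes with the lowest GC content to -0.31 in the 10% with the highest. Of the calls, 92% in the first of these bins and 14.6% in the last were higher in the libraries labelled Tnf-deleted. Once the GC trend of each library had been removed, 1354 genes were called, of which 1045 were also called without the correction, all in the same direction.

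**Figure D2:**
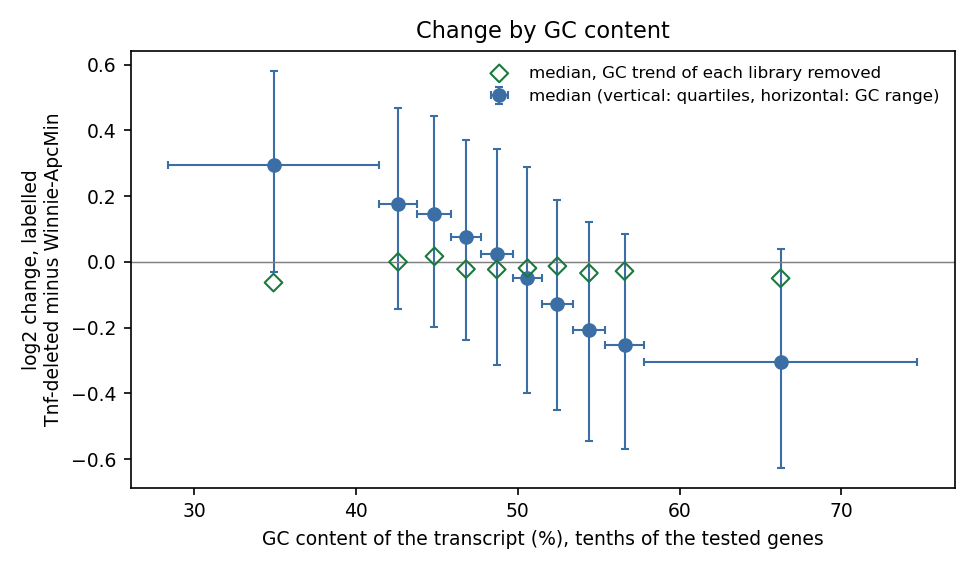
Log2 change between the groups, labelled Tnf-deleted minus Winnie-ApcMin, for 10 equal bins of the tested genes by GC content of the transcript in percent. Filled points are medians, from 0.29 to -0.31, with quartiles as vertical and the GC range as horizontal bars, and open diamonds are medians after the GC trend of each library was removed, from -0.06 to 0.02.

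Among the 12 genes with the largest rise, apart from the Y-linked genes and 5 mitochondrial transcripts, were Adcy8, Neat1 and Hddc2. Adcy8 (chromosome 15, 64697084 to 64922296), an adenylyl cyclase gene, rose from 153.5 ± 49.2 to 586.6 ± 170 normalised reads (SD, n = 3 each), a log2 change of 1.94 ± 0.28 (SE, adjusted p = 0.00507). Hddc2, which encodes an HD domain protein, rose by 1.77 ± 0.16 (SE, adjusted p = 0.000301). Neat1, the non-coding RNA of nuclear paraspeckles, rose by 1.84 (adjusted p = 0.0109), a call lost without the library labelled Tnf-deleted replicate 2 (adjusted p = 0.0517). A second set, chosen after the values were seen, left out sex-linked, mitochondrial, non-coding, haemoglobin and histone genes. It added Hsph1, a heat shock protein gene, with a log2 change of 1.57 (adjusted p = 0.00507). It also added Muc3, a membrane mucin gene, with 102.5 ± 9.07 normalised reads in Winnie-ApcMin and 280.2 ± 16.7 in the libraries labelled Tnf-deleted (SD, n = 3 each, log2 change 1.44, adjusted p = 0.00283).

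Genes with the largest fall included Clca1, which encodes a secreted goblet cell protein that processes mucus. Clca1 (chromosome 3, 145003817 to 145032776) fell from 2355 ± 693 to 658.8 ± 155 normalised reads (SD, n = 3 each), a log2 change of -1.82 ± 0.25 (SE, adjusted p = 0.00497). The phosphate transporter gene Slc34a2 had a log2 change of -2.31 ± 0.41 (SE, adjusted p = 0.00887) and the sugar transporter gene Slc2a8 one of -1.92 (adjusted p = 0.00542). The ephrin receptor gene Ephb6 had a log2 change of -1.85 (adjusted p = 0.00507) and Rabac1, which encodes a Rab-binding protein of the Golgi, one of -1.79 (adjusted p = 0.00198). Ces2c, a carboxylesterase gene, had a log2 change of -1.97 (adjusted p = 0.0174). Its call was lost without Winnie-ApcMin replicate 2 and without the library labelled Tnf-deleted replicate 3 (highest adjusted p = 0.0614). Of the other genes in this group of 12, Xist is given above, and n-R5-8s1, Hba-a2, Hba-a1, Hbb-bs and Hist1h2ad are ribosomal RNA, haemoglobin and histone transcripts. The call of Hist1h2ad was lost without Winnie-ApcMin replicates 2 or 3 and without the library labelled Tnf-deleted replicate 3 (highest adjusted p = 0.0879), and that of Hbb-bs is taken up below.

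Smooth muscle genes were lower as a group. Of 30 tested members, 11 fell (13 adjusted over the list alone), 19 did not pass, and the median log2 change was -0.695, or -0.544 after removal of the GC trend. Camera called the list with an adjusted p = 4.65e-07 and adjusted p = 0.647 with an estimated correlation. Tagln, which encodes the actin-binding protein transgelin, fell from 2965 ± 965 to 1007 ± 213 normalised reads (SD, n = 3 each), a log2 change of -1.53 (adjusted p = 0.00603). Jph2, a junctional protein gene of muscle, had a log2 change of -1.61 (adjusted p = 0.00603). The myosin light chain kinase gene Mylk had a log2 change of -0.98 (adjusted p = 0.0129), and the myosin light chain gene Myl9 one of -1.06 (adjusted p = 0.0149). Without the library labelled Tnf-deleted replicate 3, Mylk and Myl9 no longer passed (highest adjusted p of the fits without 1 library 0.0629 and 0.0518). Mylk was also lost without Winnie-ApcMin replicate 2 and without the library labelled Tnf-deleted replicate 2.

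Of 31 tested genes of fibroblasts and extracellular matrix, 5 fell (7 adjusted over the list alone), with a median log2 change of -0.58. That median rested on Winnie-ApcMin replicate 1, the library apart on the second component, and was -0.17 without it (camera adjusted p = 0.0312) and -0.87 without Winnie-ApcMin replicate 3. Of 18 genes of enteric neurons and glia, 3 fell (7 adjusted over the list alone), with a median of -0.72, and of -0.47 without Winnie-ApcMin replicate 1. Camera gave adjusted p = 3.66e-05 and adjusted p = 0.000707 for these lists, and for both adjusted p = 0.647 with an estimated correlation. Fbln1, an extracellular matrix gene, had a log2 change of -1.31 (adjusted p = 0.00973) and L1cam, a neural adhesion molecule gene, one of -0.71 (adjusted p = 0.0129). The call of L1cam was lost without the library labelled Tnf-deleted replicate 3 (adjusted p = 0.0631). Of 17 endothelial genes, 2 fell (2 adjusted over the list alone), among them the tight junction gene Cldn5 with a log2 change of -2.14 (adjusted p = 0.0197). The endothelial list passed (median -0.32, camera adjusted p = 0.0323, and adjusted p = 0.647 with an estimated correlation). It was lost after removal of the GC trend (adjusted p = 0.086), where the median was -0.285, with an SD of 0.517 over members against 0.563 before. It was also lost without Winnie-ApcMin replicate 1 (0.397), Winnie-ApcMin replicate 2 (0.0535) or the library labelled Tnf-deleted replicate 2 (0.105), and with the filter at a mean of at least 50 normalised reads (0.124). Its median was -0.18 without Winnie-ApcMin replicate 1 and -0.58 without Winnie-ApcMin replicate 3. Cldn5 was lost in 5 of the 6 fits that left out 1 library, all but that without the library labelled Tnf-deleted replicate 1 (highest adjusted p = 0.0755). Of 7 adipocyte genes, 1 fell (1 adjusted over the list alone), and that list did not pass with all libraries (adjusted p = 0.0538) but did without Winnie-ApcMin replicate 3 (0.0416) or the library labelled Tnf-deleted replicate 3 (0.0348).

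**Figure D3:**
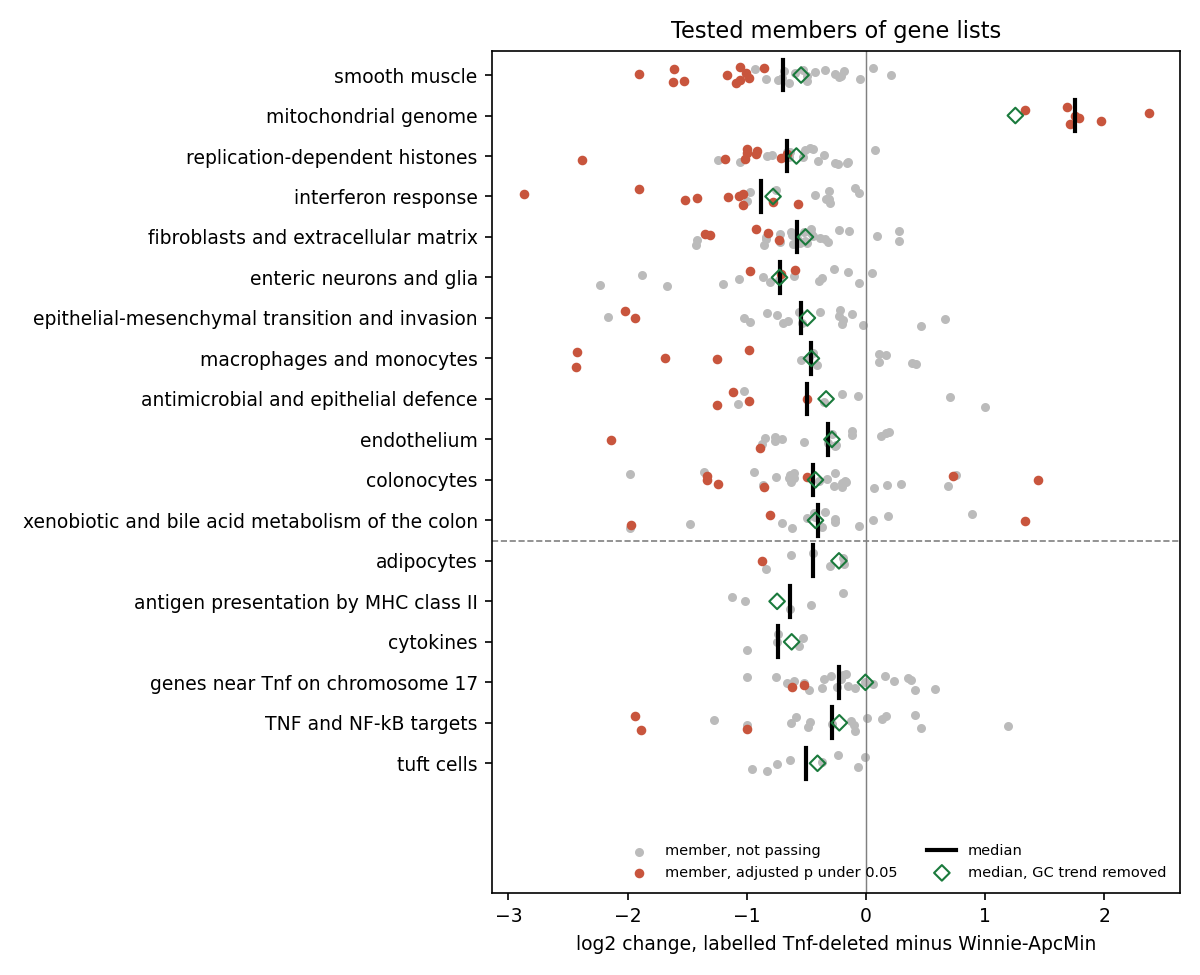
Log2 change, labelled Tnf-deleted minus Winnie-ApcMin, of the tested members of the 18 gene lists with the smallest camera p, 1 point per gene, red where the adjusted p was under 0.05. Black bars are medians and green diamonds medians after removal of the GC trend. The 12 lists above the dashed line passed camera with a preset correlation, 11 of them with a negative and 1 with a positive median, and 0 lists passed with an estimated correlation.

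Interferon-response genes were lower in the libraries labelled Tnf-deleted. All 20 tested members had a negative log2 change, 10 of them past the threshold (10 adjusted over the list alone), with a median of -0.88, and of -0.78 after removal of the GC trend. Camera gave an adjusted p = 2.42e-05 and adjusted p = 0.647 with an estimated correlation. Rsad2, which encodes the antiviral protein viperin, fell from 48.1 ± 26.5 to 5.47 ± 2.53 normalised reads (SD, n = 3 each), a log2 change of -2.87 (adjusted p = 0.00717). The guanylate-binding protein gene Gbp2 (log2 change -1.16, adjusted p = 0.0339), Ifit2 (-1.51, adjusted p = 0.0238) and Socs1, an inhibitor of cytokine signalling (-1.90, adjusted p = 0.028), passed with all 6 libraries but depended on single ones. The calls of Gbp2 and Ifit2 were lost without Winnie-ApcMin replicate 3 and without the libraries labelled Tnf-deleted replicates 2 or 3 (highest adjusted p 0.101 and 0.0803). That of Gbp2 was also lost without Winnie-ApcMin replicate 1, and that of Socs1 without any of the 6 (highest adjusted p = 0.104). It also missed the threshold after removal of the GC trend (adjusted p = 0.0515), with a log2 change of -1.65 ± 0.49 against -1.90 ± 0.48 (SE).

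Macrophage genes were lower in part. Of 14 tested members, 9 had a negative and 5 a positive log2 change, and 5 fell past the threshold (5 adjusted over the list alone), with a median log2 change of -0.46. The list passed with a camera adjusted p = 0.0211 and adjusted p = 0.647 with an estimated correlation. It was lost without Winnie-ApcMin replicate 1 (adjusted p = 0.0552) and with the filter at a mean of at least 50 normalised reads (0.124). Adgre1, the gene of the macrophage surface protein F4/80, fell from 53 ± 5.61 to 9.25 ± 3.06 normalised reads (SD, n = 3 each), a log2 change of -2.43 (adjusted p = 0.00468). The folate receptor gene Folr2 had a log2 change of -2.43 (adjusted p = 0.00507). All 5 tested genes of antigen presentation by MHC class II had a negative change, but none passed (1 adjusted over the list alone). The list missed the threshold with all libraries (median -0.64, camera adjusted p = 0.0643). It passed without Winnie-ApcMin replicate 3 (0.0483) or the library labelled Tnf-deleted replicate 1 (0.00896), with a median of -0.87 in the latter fit. The median was -0.34 without Winnie-ApcMin replicate 2 (0.372) and -0.38 without the library labelled Tnf-deleted replicate 2 (0.204). The T and NK cell list of 8 genes did not pass (camera adjusted p = 0.558, with a median of -0.08 but a mean of 0.15). The sign of that median depended on single libraries, since it was 0.17 without Winnie-ApcMin replicate 2 and 0.15 without the library labelled Tnf-deleted replicate 2. The list member Bcl11b, a transcription factor gene of T cells, rose by 1.32 (adjusted p = 0.0109, 2 members higher adjusted over the list alone). None of 9 B and plasma cell genes passed, also adjusted over the list alone (camera adjusted p = 0.626).

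Targets of TNF and NF-kB had a median log2 change of -0.285, and 3 of 19 fell (3 adjusted over the list alone), but the list did not pass (camera adjusted p = 0.101). Its median was -0.10 without Winnie-ApcMin replicate 1 (adjusted p = 0.397), and -0.45 without Winnie-ApcMin replicate 3, where it passed (adjusted p = 0.0416). It was -0.44 without the library labelled Tnf-deleted replicate 1 (adjusted p = 0.0616). Mmp9, a matrix metalloproteinase gene, had a log2 change of -1.94 (adjusted p = 0.0169). The others were Tnfaip3, which encodes the NF-kB inhibitor A20 (-0.99, adjusted p = 0.0204), and Nfkbie, another NF-kB inhibitor gene (-1.89, adjusted p = 0.0396). Each lost its call without the library labelled Tnf-deleted replicate 2. Mmp9 was also lost without replicate 3 of that group (highest adjusted p = 0.07), and Tnfaip3 without its replicate 1 or Winnie-ApcMin replicate 2 (highest adjusted p = 0.0638). With 1 library left out, Nfkbie passed only without the library labelled Tnf-deleted replicate 1 (highest adjusted p = 0.149), and it missed the threshold after removal of the GC trend (adjusted p = 0.0573), with a log2 change of -1.69 ± 0.52 against -1.89 ± 0.54 (SE). None of 5 tested cytokine genes passed, also adjusted over the list alone (camera adjusted p = 0.071, and 0.0483 without Winnie-ApcMin replicate 3). Of 3 tested TNF superfamily members, too few for camera, Tnfrsf21 fell (log2 change -0.94, adjusted p = 0.0175, 1 higher and 1 lower adjusted over the list alone). It was lost without the library labelled Tnf-deleted replicate 3 (adjusted p = 0.0803). Tnfrsf1a, the TNF receptor gene, had 34.1 ± 23.1 and 25.4 ± 11.4 normalised reads (SD, n = 3 each, adjusted p = 0.808). Of 11 antimicrobial and epithelial defence genes, 4 fell (6 adjusted over the list alone). Among them was the scavenger receptor gene Dmbt1, from 42790 ± 16240 to 20974 ± 3942 normalised reads (SD, n = 3 each, log2 change -0.98, adjusted p = 0.0311). The call of Dmbt1 was lost without any 1 of the libraries labelled Tnf-deleted (highest adjusted p = 0.115). It also missed the threshold after removal of the GC trend (adjusted p = 0.0515), with a log2 change of -0.91 ± 0.25 against -0.98 ± 0.25 (SE). That list had a median of -0.498 and a camera adjusted p = 0.0296, with adjusted p = 0.647 with an estimated correlation. It was lost after removal of the GC trend (0.0618), where the median was -0.334, with an SD of 0.702 over members against 0.757 before, and without Winnie-ApcMin replicate 2 (0.0967) or the library labelled Tnf-deleted replicate 2 (0.103), and its median was -1.05 without Winnie-ApcMin replicate 3.

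Epithelial genes changed in part. Of 30 colonocyte genes, 5 fell and 2 rose (8 and 3 adjusted over the list alone), with a median log2 change of -0.44. Of 18 genes of xenobiotic and bile acid metabolism, 2 fell and 1 rose (2 and 1 adjusted over the list alone), with a median of -0.40. Both lists had a camera adjusted p = 0.046 and adjusted p = 0.647 with an estimated correlation. Both were lost without Winnie-ApcMin replicate 2 (0.0535 and 0.0967) or without the library labelled Tnf-deleted replicate 2 (0.159 and 0.103). Both also missed the threshold with the filter at a mean of at least 50 normalised reads (0.069 and 0.0604). The second was also lost without Winnie-ApcMin replicate 3 (0.0855). Mep1a, a brush border protease gene, fell from 356.4 ± 93.6 to 137.6 ± 6.3 normalised reads (SD, n = 3 each), a log2 change of -1.33 (adjusted p = 0.00542). Goblet cell genes showed no common direction, and 3 of 23 fell (3 lower and 1 higher adjusted over the list alone). The median was 0.01 and the mean -0.11, and camera gave an adjusted p = 0.626. Without Winnie-ApcMin replicate 1 the median was -0.29 (adjusted p = 0.0552). Besides Clca1, these were Fcgbp, which encodes a mucus protein, from 42258 ± 6317 to 17123 ± 4522 normalised reads (SD, n = 3 each, log2 change -1.33, adjusted p = 0.00507), and the bestrophin gene Best2 (-1.46, adjusted p = 0.023). The call of Best2 was lost without Winnie-ApcMin replicate 3 or the libraries labelled Tnf-deleted replicates 2 or 3 (highest adjusted p = 0.0912). Of 25 genes of epithelial junctions and keratins, 2 fell (2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.83). These were the plakophilin gene Pkp3 (-0.83, adjusted p = 0.00751) and the claudin gene Cldn3 (-1.21, adjusted p = 0.00973).

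Wnt targets and stem cell genes did not pass as lists. Of 26 members of the list of Wnt and beta-catenin targets, which also holds the gene of beta-catenin itself, 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.731). Of 15 intestinal stem cell genes, 2 rose (3 adjusted over the list alone, camera adjusted p = 0.151). Notum, which encodes a secreted Wnt inhibitor, rose from 10.3 ± 7.8 to 45 ± 18.9 normalised reads (SD, n = 3 each), a log2 change of 2.15 (adjusted p = 0.0213). The other members of the Wnt list that rose were Axin2 (0.84, adjusted p = 0.0341) and Rnf43 (0.94, adjusted p = 0.0229), and 21 did not pass. Axin2 and Rnf43 are also the 2 stem cell genes that rose, so the lists share these calls. Lgr5, the stem cell receptor gene, had a log2 change of 0.85 that did not pass (adjusted p = 0.0573). The 2 members that fell were Ctnnb1 and Ephb2. Ctnnb1, which encodes beta-catenin, fell from 13952 ± 1362 to 8283 ± 734 normalised reads (SD, n = 3 each), a log2 change of -0.75 (adjusted p = 0.0077). Ephb2 had a log2 change of -0.62 (adjusted p = 0.0188), a call that ended after removal of the GC trend (-0.42, adjusted p = 0.0653). After that correction Notum (adjusted p = 0.0146), Axin2 (0.012) and Rnf43 (0.00738) still passed. Calls of Notum, Axin2 and Rnf43 were lost without the libraries labelled Tnf-deleted replicate 1 or replicate 3 (highest adjusted p 0.0869, 0.0997 and 0.108). That of Axin2 was also lost without Winnie-ApcMin replicates 1 or 3 and that of Rnf43 without Winnie-ApcMin replicate 2. Ctnnb1 passed in all 6 fits that left out 1 library.

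The list of epithelial-mesenchymal transition and invasion, with 2 of 20 genes lower (2 adjusted over the list alone), had a median log2 change of -0.55 and a camera adjusted p = 0.0139, with adjusted p = 0.647 with an estimated correlation. It was lost without Winnie-ApcMin replicate 1, where the median was -0.11 (adjusted p = 0.204), and the median was -0.91 without Winnie-ApcMin replicate 3. With the filter at a mean of at least 50 normalised reads it was lost too (median -0.305, adjusted p = 0.0713). The 2 lower genes were Mmp9 and the urokinase gene Plau (log2 change -2.02, adjusted p = 0.0369). The call of Plau was lost in each of the 6 fits that left out 1 library (highest adjusted p = 0.104). Cell cycle genes did not pass as a list (2 of 33 higher and 1 lower, 2 and 0 adjusted over the list alone, camera adjusted p = 0.83). Nor did those of the unfolded protein response (1 of 28 higher and 2 lower, 1 and 2 adjusted over the list alone, camera adjusted p = 0.795, median -0.02 and mean 0.09). The proliferation marker gene Mki67 rose by 0.92 (adjusted p = 0.029) while the cyclin gene Ccnb1 had a log2 change of -0.92 (adjusted p = 0.0424). Both were lost without Winnie-ApcMin replicates 2 or 3 and without the libraries labelled Tnf-deleted replicates 2 or 3, and Ccnb1 also without replicate 1 of the latter (highest adjusted p 0.0902 and 0.161).

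Some classes of transcripts, among them some that can vary with RNA quality or capture, also differed between the groups. Others shifted little, with a median log2 change of 0.001 for 48 small nucleolar RNA genes (2 higher and 6 lower). It was -0.121 for 299 processed pseudogenes (13 higher and 21 lower). Of 4 tested genes like ribosomal RNA, 1 was higher and 3 were lower. Of 9 tested genes of the mitochondrial genome, 8 rose, with a median log2 change of 1.71. Of the 13 genes in the list of its protein-coding genes only 7 were in the table and could be tested. These 7 all rose (7 adjusted over the list alone), and the list had a camera adjusted p = 5.01e-07, with adjusted p = 0.647 with an estimated correlation. Its median of 1.75 over these genes became 1.25 after removal of the GC trend. The exception was mt-Rnr2, the large ribosomal RNA, with 78812 ± 10307 and 87936 ± 24516 normalised reads (SD, n = 3 each, adjusted p = 0.709). Nuclear genes of oxidative phosphorylation did not pass as a list, with 4 of 35 lower (4 adjusted over the list alone, camera adjusted p = 0.4, and 0.0272 without Winnie-ApcMin replicate 1, with a median of -0.22). Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, were lower, with 9 of 27 past the threshold (11 adjusted over the list alone). The list had a median of -0.66 and a camera adjusted p = 5.01e-07, with adjusted p = 0.647 with an estimated correlation. Without the library labelled Tnf-deleted replicate 2 the median was -0.32 (camera adjusted p = 2.25e-05). Hist1h2bb had a log2 change of -1.02 (adjusted p = 0.00717), and the ribosomal RNA copy n-R5-8s1, which shares its sequence with other copies and is therefore uncertain, one of -3.56 (adjusted p = 0.00066). Of 4 tested red blood cell genes 3 fell (3 adjusted over the list alone), and these were the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, with a median of -2.49. The reads of Hba-a1 and Hba-a2 may be split between near-identical copies. The call of Hbb-bs was lost without Winnie-ApcMin replicates 1 or 2 and without the libraries labelled Tnf-deleted replicates 2 or 3 (highest adjusted p = 0.111).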

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

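The alternatives chosen after the data were seen were the pseudocounts, TMM scaling, GC correction, thinning, and the fit without X, Y and mitochondrial genes. In the design fixed before the data were examined, edgeR with TMM factors and camera on voom values were the main tests. They became alternatives when limma and camera without voom weights took their place, after the values were seen not to be raw counts. No named gene and no list changed direction past a threshold under any alternative run. Of the values of named genes under the alternatives 3061 kept their side of the threshold, 281 lost and 52 gained a call. Of those of lists 560 kept it, 47 lost and 15 gained one. Counts of genes, 814 higher and 712 lower, became 1299 and 1379 with limma-voom and quality weights, 1319 and 1286 at an adjusted p under 0.1, and 210 and 284 at a change of at least 2-fold, by construction for the last pair. Leaving out 1 library gave 186 to 748 higher and 138 to 649 lower genes, lowest without the library labelled Tnf-deleted replicate 3, and fewer libraries also mean fewer degrees of freedom. Other tools, scalings, filters and pseudocounts stayed within 1.5 times, and their direction split stayed between 48.2% and 54.5% higher. Lists with a lower call, 11, became 7 at a mean of at least 50 normalised reads, where fewer genes were tested, and 0 with an estimated correlation and 0 with fry (0 and 4 of all lists at an unadjusted p under 0.05), and 7 to 16 without 1 library. The single list with a higher call became 0 with an estimated correlation, 0 with fry and 0 without X, Y and mitochondrial genes, which removes that list by construction, and 1 to 2 without 1 library. The cause of the other moves was not tested. The log2 difference of Tnf, 2.15, was 2.83 at a pseudocount of 0.5, 0.83 at a pseudocount of 5 and 1.67 after thinning, and 1.95 to 2.4 without 1 library, since counts of 1 and 11 reads leave it to the pseudocount. The first component held 48.1 to 55.2% and separated the groups in every variant run. Replicate numbers did not pair the libraries. Deviations from the group means of same-numbered libraries correlated at 0.07, -0.08 and 0, and 2 of 6 libraries were closest to their own number. With the replicate number as a block, 577 genes were higher and 539 lower, with 10 lists lower and 1 higher. The block ended the call of the xenobiotic and bile acid list (adjusted p = 0.0539, against 0.00869 to 0.103 over the fits without 1 library) and of 16 named genes, and 3 named genes gained one. Depth limits genes near the floor such as Tnf, with at most 5 reads in a library.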

Other observations

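The tests of gut wall content and of its common factor, of sex, of a mislabelled library and of sex behind autosomal genes were chosen after their results had been seen, and so were the GC and thinning fits as alternatives and the single genes named here outside the fixed rule.

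Genes of the chromosome 17 region that holds Tnf and the H2 complex were examined apart. Within 5 Mb of Tnf 23 of 129 tested genes (17.8%) passed, against 1402 of 10341 other autosomal genes (13.6%, Fisher's exact two-sided p = 0.16). Of the 26 tested genes of the fixed list near Tnf 2 fell (1 adjusted over the list alone), Bag6 with a log2 change of -0.62 (adjusted p = 0.0185) and Clic1 with -0.52 (adjusted p = 0.0463), and both calls ended after removal of the GC trend as the changes shrank, from -0.62 ± 0.14 to -0.36 ± 0.11 and from -0.52 ± 0.15 to -0.32 ± 0.14 (SE). Bag6 was also lost without Winnie-ApcMin replicate 2 or the libraries labelled Tnf-deleted replicates 2 or 3 (highest adjusted p = 0.077), and Clic1 in every fit without 1 library except that without Winnie-ApcMin replicate 3 (highest adjusted p = 0.159). The list did not pass (median -0.225, camera adjusted p = 0.071), and its median was -0.004 after removal of the GC trend (adjusted p = 0.843). Without 1 library it was -0.10 without Winnie-ApcMin replicate 1, -0.13 without the library labelled Tnf-deleted replicate 2, and -0.37 without the library labelled Tnf-deleted replicate 1, where the list passed (adjusted p = 0.0217). Of 20 tested H2 genes, examined after their values were seen, 14 did not pass, 2 were higher and 4 lower. H2-Bl had a log2 change of 4.35 (limma adjusted p = 0.0136) and H2-T10 one of 1.70 (0.00647), whereas H2-T22 had -1.49 (0.00283), H2-T23 -1.41 (0.00542), H2-Q6 -1.63 (0.0388) and H2-M3 -0.76 (0.0413). H2-Bl had 2.29 ± 3.97 normalised reads in Winnie-ApcMin and 47.8 ± 32.6 in the libraries labelled Tnf-deleted (SD). The first mean lies near the floor of 3 reads per library, so the size of this change depends on the pseudocount. Calls were lost without the library labelled Tnf-deleted replicate 3 for H2-Bl (adjusted p = 0.0608), without any 1 of the 6 libraries for H2-M3 (highest 0.126), and without Winnie-ApcMin replicates 1 or 2 or the libraries labelled Tnf-deleted replicates 2 or 3 for H2-Q6 (highest 0.134). Those of H2-Q6 and H2-M3 also missed the threshold after removal of the GC trend (adjusted p 0.0532 and 0.0515), with log2 changes of -1.44 ± 0.41 against -1.63 ± 0.43 and of -0.70 ± 0.21 against -0.76 ± 0.22 (SE). The calls of H2-T10, H2-T22 and H2-T23 were kept in all 6 fits without 1 library (highest adjusted p 0.0445, 0.018 and 0.0254). They were also kept after removal of the GC trend (adjusted p 0.00656, 0.00254 and 0.00574). The H2 genes have near-identical copies between which reads can be split, so their values are uncertain.

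Cytosolic ribosomal protein genes moved in both directions, with 9 of 71 higher and 8 lower (10 and 11 adjusted over the list alone, camera adjusted p = 0.795). Rpl12 rose by 0.90 (adjusted p = 0.00603), while Rps21 had a log2 change of -1.35 (adjusted p = 0.00507) and Rpl10a one of -1.09 (adjusted p = 0.00402). Genes of distal colon position had a median of 0.34, with 1 of 9 higher (0 adjusted over the list alone, camera adjusted p = 0.196). This median was -0.42 without Winnie-ApcMin replicate 2 (0.664), so its direction depended on 1 library. It was 0.22 without the library labelled Tnf-deleted replicate 2, and 0.65 without Winnie-ApcMin replicate 1, where the list passed (0.0398). Anterior Hox genes had a median of 0.62 and a mean of 0.19, with 2 of 11 higher (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.164), and a median of 0.21 without Winnie-ApcMin replicate 2. Immediate early and stress genes, with 1 higher and 1 lower of 25 (1 and 0 adjusted over the list alone, adjusted p = 0.558), apoptosis and necroptosis genes, with 1 higher of 21 (1 adjusted over the list alone, adjusted p = 0.683), enteroendocrine genes, with 1 higher and 1 lower of 16 (1 and 1 adjusted over the list alone, adjusted p = 0.795), and tuft cell genes, with 0 of 8 (0 adjusted over the list alone, adjusted p = 0.117), did not pass camera. Without Winnie-ApcMin replicate 3 the immediate early list (0.0404) and the tuft cell list (0.0466) passed. In the lists too short for camera, 1 neutrophil gene of 3 was higher and 1 lower (1 and 1 adjusted over the list alone), and 0 of 2 lymphoid follicle genes passed (1 and 1 adjusted over the list alone).

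Xist and the Y-linked genes divided the libraries by group. A single mislabelled library would have the Xist and Ddx3y pattern of the other group, and 0 libraries did, although Winnie-ApcMin replicate 1 alone of its group held Y-linked reads, 8 of Eif2s3y and 1 of Uty beside 238 of Xist and 0 of Ddx3y. All 6 libraries followed their group. Xist had 238, 216 and 311 reads in Winnie-ApcMin and 0 in each library labelled Tnf-deleted. Ddx3y had 0 reads in each Winnie-ApcMin library and 2066, 2353 and 2469 in the libraries labelled Tnf-deleted. The groups thus differed in these transcripts as female and male mice do, although the labels give no sex. Sex and deletion of Tnf cannot be told apart as sources of the 1425 autosomal calls, because no group holds libraries with both patterns. An exchange of all labels between the groups would reverse the sign of every change and leave each library like its group, so the 0 libraries above do not address it, and the Tnf reads, 1 against 11, leave it open because the deleted part of the gene is not given.

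The number of called genes may reflect genotype, sex or technical differences between the groups. The GC trend as its whole cause is argued against by the 1354 genes called after its removal, 1045 of them among the 1526 called before, while for the 481 calls that ended a contribution of base composition stays open. The lower depth as whole cause is argued against by the 1436 called after thinning, 1361 of them among the 1526. In 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, as many genes were called, with 0 in the highest of the others by limma (82 to 589 at an unadjusted p under 0.05) and 0 by edgeR, and in 6 of 10 as many lists, with 12 in the real and 20 in the highest other split. For the genes, 10 splits in all are too few for a share under 0.05. Every other split also mixes the groups on both sides, which widens the spread within a side, so its 0 calls decide nothing. For the lists, 6 of 10 splits gave as many, so the number of lists called does not set the real split apart from the others.

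The smooth muscle list was lower in the libraries labelled Tnf-deleted, with adjusted p = 0.647 with an estimated correlation. The GC trend as whole cause is argued against by the median log2 change of the list after its removal, -0.544. Less gut wall in the dissected tissue stays open. After that correction the list of enteric neurons and glia had a median of -0.725, and 1 of its 18 genes passed. This list did not pass camera with an estimated correlation (adjusted p = 0.675), but 0 of the tested lists did then, so this outcome cannot decide the question. A loss that lowers every muscle transcript by 1 factor is not decided either. Of the 6 genes Acta2, Myh11, Actg2, Des, Cnn1 and Tagln, 4 departed from their joint mean by over 2 SE with groups that do not overlap. These departures are of values after removal of the GC trend. Des and Tagln departed by -0.438 ± 0.147 and -0.455 ± 0.093, and Myh11 and Cnn1 by 0.457 ± 0.195 and 0.542 ± 0.199 (SE). The positive departures are smaller falls, not rises. After that correction Myh11 had a log2 change of -0.499 (limma adjusted p = 0.254) and Cnn1 one of -0.414 (0.269). Neither passed before it (0.152 and 0.184). Departures from a mean of the same 6 genes depend on each other, and 2 SE is a loose limit with 3 libraries per group. A different share or state of muscle, sex and deletion of Tnf stay open.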
